A study of Mus musculus with 4 samples.

How the data were processed

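The samples are 4 libraries of mouse liver cells after carbon tetrachloride, 2 labelled wild type and 2 labelled Ythdf3 knockout, made with the 10x Genomics 3′ v3 chemistry per the labels' protocols. The authors aligned and counted them with Cell Ranger 6.1.0 on GRCm39, per the file headers and the submitters' processing notes. The deposited values are raw UMI counts per gene and cell barcode, with no normalization. The deposited dense tables hold the same counts: 0 of their rows differed from the matrices, and they were not used further. Barcodes had been filtered before deposit, since each has at least 500 UMIs, and the annotation release and cell calling settings are not stated. The files list 56884 genes, and 147 symbols occur more than once; genes sharing a symbol were kept apart by their identifiers.

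Cells were kept with at least 500 UMIs, at least 300 genes and under 25% mitochondrially encoded UMIs. Doublets were marked with scrublet per library (expected rate 0.8% per 1000 cells, automatic threshold, seed 0) and removed, which left 27980 of 29964 barcodes. Counts were scaled to 10000 per cell and log transformed. Clustering used 2000 variable genes, values limited to 10 after scaling, 30 principal components, 15 exact nearest neighbours and Leiden at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15), without batch integration. Clusters were given a class by hand, after their leading genes were seen, from marker lists fixed before the data were examined, and the ending "-like" marks these classes. The Conventional DC-like class joins the markers of both conventional dendritic cell types, and the Mesenchymal-like class those of stellate cells and of portal fibroblasts or mesothelium. Clusters without a clear set of markers, or with markers of more than 1 class, kept their number or leading gene as a name. The hepatocyte share follows the 50 g spin named in the protocol.

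For expression, UMI counts were summed per library over all kept cells and within each of the 15 classes with at least 20 cells in every library, so that the library is the replicate. Knockout was compared with wild type in edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05 within a class; CPM use library sizes after TMM, and raw CPM do not. All fold changes are knockout over wild type. Class shares were tested with the same quasi-likelihood test on cell numbers, without TMM and without a dispersion trend. Gene lists with at least 4 measured genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and again with an estimated correlation and with fry. Dividing cells were those with a UMI of Mki67 or Top2a after thinning to 1000 UMIs, compared by an exact permutation test.

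The genes to be named were set by a rule written before the data were examined. It takes Ythdf3, Ythdf1, Ythdf2, Cebpa and Cebpb; then, per class, up to 8 genes in each direction with the largest log2 fold change among those past the threshold with at least 20 CPM in the higher genotype and both knockout libraries on the same side of both wild-type libraries; where none passed, the 3 higher and 3 lower genes with the smallest p, given as values that did not pass; and up to 4 members of each list that passed, with at most 30 genes per class. Predicted genes, pseudogenes, immunoglobulin and T cell receptor segments, and mitochondrial, ribosomal, haemoglobin and sex-linked genes are outside the second part of the rule.

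The procedure was tested on simulated counts with 200 changed genes, drawn among genes with a mean of at least 20 CPM. Recovery of genes at lower levels was not tested. Among all cells 88% of genes changed 2-fold were recovered and 99% of those changed 4-fold, with 18 false calls of 205; among Monocyte/macrophage-like cells 90% and 100%, with 19 of 209; among T cell-like cells 51% and 99%; and among Mesenchymal-like cells 5% and 66%. Low calls in small classes therefore say little about 2-fold changes. The simulated counts used the fitted dispersions and changed 200 genes at once, so these shares may overstate recovery in the real counts. Over all cells Ifit3, Ifit1 and Isg15 rose more than 2-fold without passing. Few calls over all cells therefore do not exclude other 2-fold changes.

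Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0's Wald test, no filter on low counts, each library left out, the replicate number as a block, no mitochondrial limit, doublets kept, Leiden at resolution 0.5, classes assigned from neighbours after ComBat, hepatocyte genes left out of the other classes, other denominators of the shares, and other thinning depths. With 2 libraries per genotype the data cannot separate genotype from anything else that differed between the mice or preparations, since the labels give no batch. Basophil-like, Cholangiocyte-like, Migratory DC-like, Saa3-high, low-UMI and unnamed clusters were left out of the expression tests for having too few cells or no class.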

Results

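Single-cell RNA sequencing of mouse liver after carbon tetrachloride, a toxin that injures hepatocytes, compared wild-type mice with mice labelled as knockouts of Ythdf3, which encodes a reader of N6-methyladenosine in RNA. Each genotype had 2 libraries. The design asks how the hepatic cell populations differ between the genotypes, and the title of the series concerns CEBPA, genomic stability and stem cell function. The liver cells had been spun at low speed, which sends hepatocytes to the pellet, so the hepatocyte share is set by the preparation. The files held 61315452 UMIs in wild-type replicate 1, 48735258 in wild-type replicate 2, 40551751 in knockout replicate 1 and 62350711 in knockout replicate 2. After filtering, 7439, 7186, 5529 and 7826 cells remained in the same order. The labels give neither the toxin's dosing schedule nor whether each library comes from its own mouse.

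The Ythdf3 transcript was not lower in the libraries labelled knockout. Ythdf3 (counted at the 3′ end) stood at 53.17 and 52.48 CPM in the wild-type libraries and at 57.18 and 56.13 CPM in the libraries labelled knockout, over 3059, 2340, 2259 and 3056 UMIs. The log2 fold change of Ythdf3 over all cells was 0.10 (95% interval -0.20 to 0.40), and between -0.25 in pDC-like cells and 0.46 in Hepatocyte-like cells across the classes, with no class past the threshold. Because the counts read only the 3′ end and no source gives the deleted part of the gene, Ythdf3 does not check the genotype labels, and "knockout" below means the libraries so labelled. Ythdf1 and Ythdf2, the other cytoplasmic readers of this family, had all-cell log2 fold changes of 0.10 (SE 0.14) and 0.08 (SE 0.15), and did not pass. Cebpa, the transcription factor of the title, had 141 CPM in wild type and 179 CPM in knockout (log2 fold change 0.34, SE 0.23), and Cebpb had 504 and 599 CPM (0.25, SE 0.21); neither passed over all cells or in any tested class.

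Clustering gave 35 clusters. Macrophages and monocytes made up the largest class in all 4 libraries, followed by B cell-like cells. Kupffer-like cells, the resident macrophages of the liver led by Clec4f, Vsig4 and Marco, made up 7.12% ± 1.93 (SD, n = 2) of the cells in wild type and 3.16% ± 0.608 in knockout, with both knockout libraries below both wild-type libraries. LSEC-like cells, the sinusoidal endothelium, made up 6.28% ± 1.47 in wild type and 3.02% ± 1.58 in knockout, and pDC-like cells 3.34% ± 0.159 and 2.43% ± 0.242. T cell-like cells made up 5.15% ± 0.232 in wild type and 7.75% ± 1.44 in knockout, Neutrophil-like cells 3.93% ± 0.204 and 5.79% ± 0.624, and B cell-like cells 10.9% ± 1.74 and 14.02% ± 2.33. None of the 25 classes passed after Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test: the adjusted p was 0.244 for Kupffer-like cells (log2 fold change -1.17), 0.433 for LSEC-like cells (-1.06) and 0.433 for T cell-like cells (0.59). The log2 fold change of LSEC-like cells was -1.72 without knockout replicate 1 and -0.60 without knockout replicate 2, that of T cell-like cells 0.39 without knockout replicate 2. The exact permutation test with 2 libraries against 2 cannot go below a two-sided p of 0.333. Monocyte/macrophage-like cells made up 31.01% ± 8.77 in wild type and 35.8% ± 2.32 in knockout, less than the spread between the wild-type libraries.

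Low-UMI cluster 16, led by haemoglobin genes and endothelial genes such as Clec4g, made up 3.62% ± 2.85 of the cells in wild type and 0.239% ± 0.00541 in knockout (log2 fold change -3.91, adjusted p 0.0902). It did not pass with TMM over the classes (0.194), without the mitochondrial limit (0.138), at Leiden resolution 0.5 (0.147) or without knockout replicate 1 (0.0927). Its median was 968 UMIs per cell against 4482.5 over all cells, but 8325 among its 19 cells in knockout replicate 2, against 766, 996 and 879 in the other libraries, so the name does not describe its cells in that library. Cluster 16 passed with hepatocytes left out of the denominator (adjusted p 0.0447), with doublets kept (0.0382, log2 fold change -2.59), without wild-type replicate 1 (1.06e-06), without wild-type replicate 2 (0.00263, log2 fold change -2.73) and without knockout replicate 2 (0.039).

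**Figure D1:**
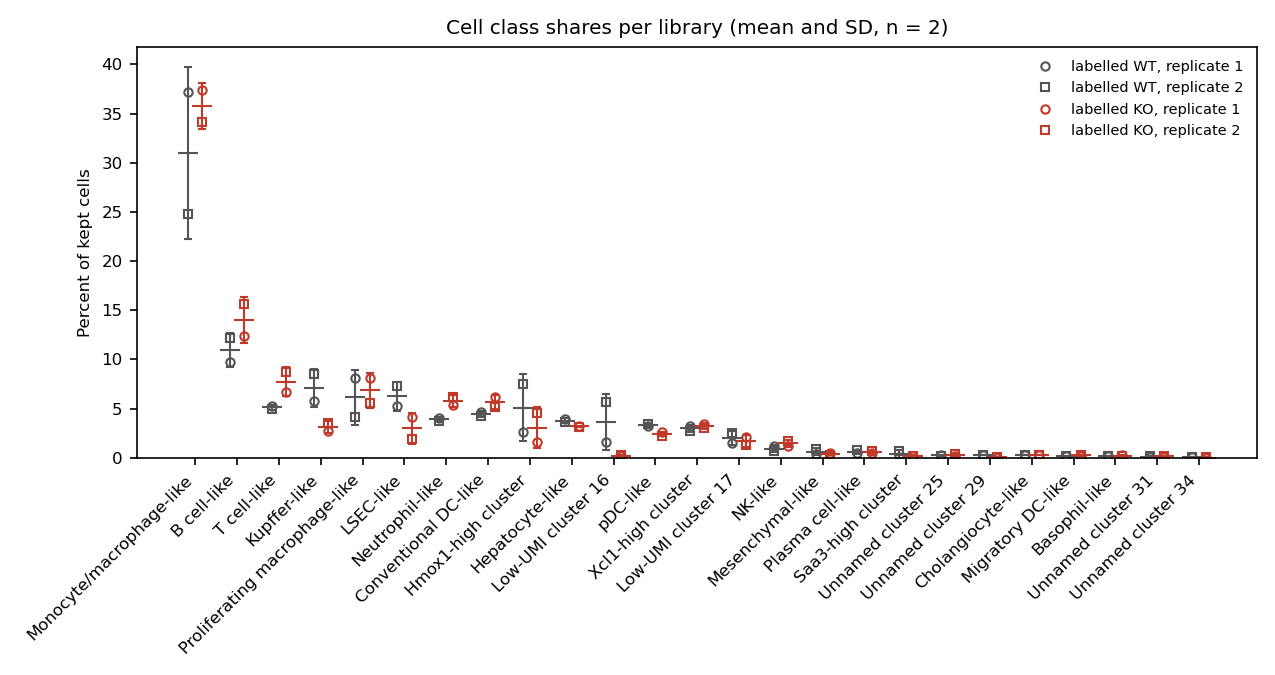
Percent of kept cells in each class (vertical axis, linear, from 0) per library, with horizontal marks for the mean and bars for the SD of the 2 libraries of each genotype. Kupffer-like cells lie at 5.75% and 8.49% in wild type and at 2.73% and 3.59% in knockout.

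Dividing cells, read from at least 1 UMI of Mki67 or Top2a after each cell was thinned to 1000 UMIs, made up 8.10% ± 1.92 (n = 2) of the cells with at least 1000 UMIs in wild type and 7.64% ± 1.36 in knockout, a difference smaller than the spread between replicates. Cells with fewer UMIs were left out, 1373 in wild type and 708 in knockout, among them 184 of 553 and 100 of 425 Hepatocyte-like cells. In Hepatocyte-like cells the share was 7.32% ± 0.524 in wild type and 4.65% ± 0.395 in knockout, and in LSEC-like cells 8.77% ± 1.75 and 4.14% ± 2.99; both knockout libraries lay below both wild-type libraries in each (two-sided exact permutation p 0.333, the smallest possible). Neutrophil-like cells, mostly mature cells that no longer divide, gave 2.67% in wild type and 1.65% in knockout. Whether this is background was not tested, since the count was not split by cluster. The class also includes cluster 30, with 40 cells led by Camp, Ngp and Ltf. The median of the class was 1305 UMIs, beside medians of 1727 in Hepatocyte-like and 4204.5 in LSEC-like cells. Hepatocyte-like cells were mostly small: cluster 12, with 945 of the 978 cells, had a median of 1663 UMIs.

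Over all cells of a library, the genes under the naming rule with the smallest p higher in knockout were interferon-induced genes, and none of them passed. Ifit3, Ifit1 and Isg15 had log2 fold changes of 1.23 (SE 0.13), 1.30 (SE 0.15) and 1.22 (SE 0.14), each with an adjusted p of 0.161. The lower genes with the smallest p were Chp2 (-1.53, SE 0.25), Wfdc2 (-1.64, SE 0.28) and Gja5 (-2.81, SE 0.48), with adjusted p of 0.362, 0.414 and 0.414. Among 17480 genes, edgeR's quasi-likelihood test called 1, the immunoglobulin segment Igkv12-46, higher in knockout; it falls outside the naming rule and is named because it is the single call. At an unadjusted p under 0.05 there were 1018 genes, 5.82% of those tested, where a share of about 0.05 would lie without any change. DESeq2's Wald test called 74 genes (43 higher and 31 lower), and edgeR called 515 without the filter on low counts; leaving out wild-type replicate 1, wild-type replicate 2 or knockout replicate 2 gave 0, 4 and 6 calls.

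Monocyte/macrophage-like cells held 26 of the 52 calls made within classes. In these cells 20 genes rose and 6 fell in knockout out of 13419 (edgeR quasi-likelihood, Benjamini-Hochberg). The 8 largest rises under the naming rule were Ly6a, Oasl1, Ifit1, Irf7, Ifit2, Ifi213, Ifit3 and Isg15, all known to be induced by interferon. Ifit3 has a near-identical copy, Ifit3b, so the split of reads between them is uncertain. Irf7, a transcription factor of the interferon response, rose from 56.3 CPM ± 1.54 to 162 CPM ± 19.8 (SD, n = 2; log2 fold change 1.53, SE 0.16, adjusted p 0.0214). Isg15, a ubiquitin-like protein, rose from 37.9 CPM ± 4.59 to 102 CPM ± 6.48 (log2 fold change 1.43, SE 0.16, adjusted p 0.0214). Ifit1, Ifit2 and Ifit3, which bind viral RNA or its partners, rose by log2 fold changes of 1.56, 1.49 and 1.46, and Ly6a by 1.61 with an adjusted p of 0.0238. No gene that fell met the naming rule in this class. The class joins 5 clusters, of which cluster 3, led by Cxcl10, Ifit3 and Isg15, held 15.7% and 14.1% of the class in wild type and 29.3% and 25.9% in knockout, and cluster 15 had none of the class markers among its 10 leading genes. DESeq2 called 74 genes. The count was 11 with doublets kept, 4 at Leiden resolution 0.5, and 0 without cluster 3. Without knockout replicate 1 or 2 most of the 26 were no longer called. Cluster 15 alone gave 24 calls, of which 11 were among the 26.

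**Figure D2:**
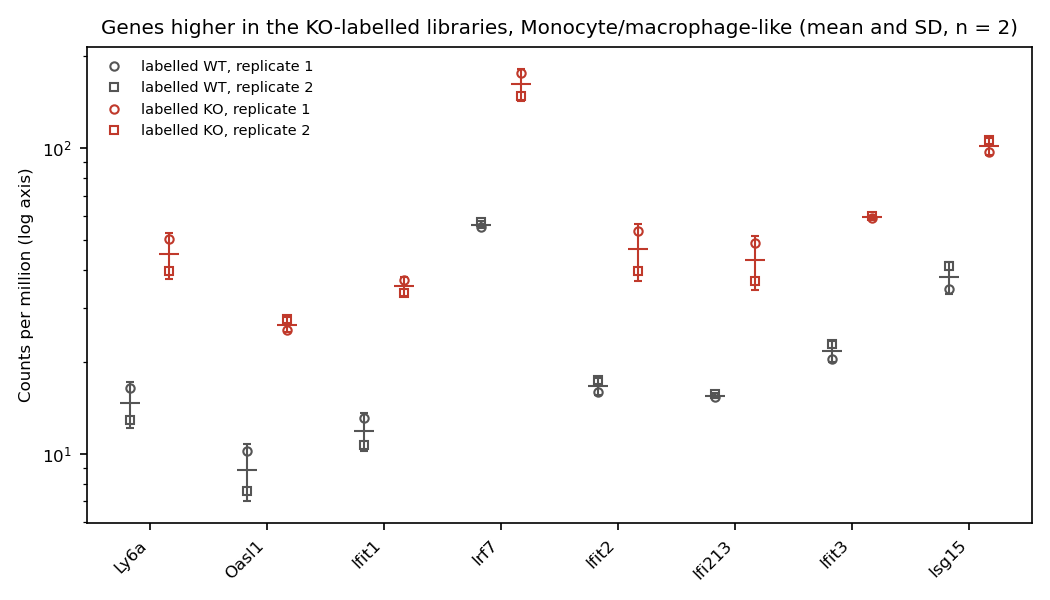
CPM (vertical axis, logarithmic) of the 8 genes with the largest rise in Monocyte/macrophage-like cells, per library, with marks for the mean and bars for the SD of 2 libraries. Both knockout libraries lie above both wild-type libraries for each gene.

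In T cell-like cells 3 genes rose and 10 fell among 8915. Ifitm1, an interferon-induced membrane protein, rose from 17.96 CPM ± 19.7 to 113 CPM ± 16.5 (n = 2; log2 fold change 2.81, SE 0.43, adjusted p 0.0208), Il1b by 1.97 (SE 0.34) and the gamma-delta T cell gene Scart1 by 1.79 (SE 0.34). Ifitm1 and Il1b are also among the 10 leading genes of the Neutrophil-like cluster 7, and the neutrophil gene S100a9 had a log2 fold change of 1.67 in T cell-like cells without passing (adjusted p 0.16), so a change within T cells was not shown. Scart1 leads cluster 23 with Trdc, and that cluster held 16 of 395 and 14 of 358 T cell-like cells in wild type and 30 of 372 and 65 of 686 in knockout. Among the genes that fell, Clec4f, Cd5l and Slc40a1 are macrophage genes that lead Kupffer-like cells or mark them, with log2 fold changes of -1.70, -1.55 and -1.57. Lars2, a mitochondrial leucyl-tRNA synthetase, fell from 1093 CPM ± 138 to 532 CPM ± 6.66 (-1.04), and Fabp4 fell by 1.84 on the log2 scale. Lars2 is among the 10 leading genes of Low-UMI cluster 17, with mt-Rnr2, mt-Co1 and Rn18s-rs5. Fabp4 is among the 10 leading genes of macrophage cluster 2 and had 3042 to 4416 CPM in LSEC-like cells. A change of Lars2 or Fabp4 within T cells was therefore not shown. In B cell-like cells 4 genes fell: the same Kupffer gene Clec4f (48.5 CPM ± 1.77 to 11.5 CPM ± 4.72, adjusted p 0.00563), Hpgd (-1.69, adjusted p 0.0256) and the haemoglobin genes Hbb-bs and Hbb-bt. The haemoglobin genes are outside the naming rule and are named because the calls are few. They are among the 10 leading genes of Low-UMI clusters 16 and 17, and cluster 16 was rarer in both knockout libraries. A change of the haemoglobin genes or of Clec4f within B cells was therefore not shown. Within Kupffer-like cells no gene passed, and the Kupffer identity list, with Clec4f among its members, had a median log2 fold change of -0.04. Without wild-type replicate 1 most of the 13 T cell-like calls were not made, and without knockout replicate 1 or 2 none was made. DESeq2 made 1 of the 13. With doublets kept 5 of the 13 T cell-like calls were made, and at Leiden resolution 0.5 the count was 0. For B cell-like cells DESeq2 called 1 gene, which was not among the 4, and the replicate block called 2, of which 1 was among the 4.

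In pDC-like cells Ccl5 rose by a log2 fold change of 2.75 (SE 0.43, adjusted p 0.00976), while Mmp12, a macrophage elastase, and Rgs1 fell by 3.60 and 1.41 on the log2 scale. The knockout libraries differed widely for Ccl5 (133 CPM ± 105), as did the wild-type libraries for Mmp12 (225 CPM ± 183). Ccl5 is also among the 10 leading genes of T cell-like cluster 5, the Xcl1-high cluster and NK-like cluster 18, and Mmp12 leads macrophage cluster 2, so a change within pDC-like cells was not shown. In the Hmox1-high cluster, led by Hmox1, Gclm and Srxn1, 4 genes rose and 1 fell, and the interferon genes Irf7 (1.18, adjusted p 0.0118) and Rtp4 (1.01, adjusted p 0.0436) were among the rises. The other calls there, named after their values were seen, were Marcksl1 (higher), Clec4f (lower) and Hbb-bs, whose knockout libraries lay on both sides of wild type (0.847 and 137.3 CPM). In Plasma cell-like cells the single call was Igkv12-46. DESeq2 called 0 genes in pDC-like cells. It called 3 in the Hmox1-high cluster, of which 1 was among the 5, and 6 in Plasma cell-like cells, with Igkv12-46 among them. All 5 calls in the Hmox1-high cluster, Irf7 and Rtp4 among them, were lost with doublets kept and with ComBat, the 3 in pDC-like cells with ComBat, and the 1 in Plasma cell-like cells without the mitochondrial limit. Leaving out wild-type replicate 1, wild-type replicate 2, knockout replicate 1 or knockout replicate 2 gave 13, 8, 27 and 71 calls in pDC-like cells, 27, 26, 20 and 18 in the Hmox1-high cluster, and 49, 0, 61 and 375 in Plasma cell-like cells.

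No gene passed in Conventional DC-like, Hepatocyte-like, Kupffer-like, LSEC-like, Mesenchymal-like, Neutrophil-like, NK-like or Proliferating macrophage-like cells or in the Xcl1-high cluster. The genes at an unadjusted p under 0.05 in edgeR's test numbered 424, 381, 516, 525, 280, 166, 123, 310 and 423 in that order. The genes tested numbered 9942, 7125, 10384, 10187, 6394, 5017, 5863, 11460 and 6823. Without any change a share of about 0.05 of them would lie under this bound, so these counts are not evidence of a difference. DESeq2 called 7, 2, 0, 8, 2, 5, 1, 3 and 3. In the same order edgeR called 1, 24, 103, 6, 34, 0, 2, 73 and 47 without wild-type replicate 1 and 0, 4, 25, 62, 16, 2, 0, 49 and 101 without wild-type replicate 2. It called 0, 0, 83, 2, 49, 29, 14, 7 and 8 without knockout replicate 1 and 0, 16, 0, 2, 6, 84, 34, 33 and 61 without knockout replicate 2. In Hepatocyte-like cells the smallest p belonged to Dbp, a clock gene, with a log2 fold change of 2.10 (SE 0.36), and to Hsp90b1 (-1.48, SE 0.24) and Hmmr (-2.20, SE 0.38), each with an adjusted p of 0.415. In Neutrophil-like cells Cxcl10 had a log2 fold change of 3.41 (SE 0.55) and Lars2 of -1.51 (SE 0.25), each with an adjusted p of 0.182. In the Xcl1-high cluster, led by Xcl1, Il2rb and Gzmc, the granzyme gene Gzma had 431 CPM ± 94.2 in wild type and 1562 CPM ± 562 in knockout (adjusted p 0.079). In Conventional DC-like cells Ccl17 and Irf7 had log2 fold changes of 2.45 and 1.09, and in LSEC-like cells Cd5l and Clec4f of -1.46 and -1.93, none past the threshold.

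Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation. Of 608 tests of a list in a class, 166 passed, 60 higher and 106 lower in knockout. With a correlation estimated from the data 0 passed, with a lowest adjusted p of 0.431, and fry's test of movement in 1 direction also gave 0, with a lowest of 0.146; fry's test of change in either direction passed in 5 of the 608. In simulated Monocyte/macrophage-like counts 1 list was raised by a log2 fold of 0.5, and camera called it. The adjusted p was 0.32 with the estimated correlation and 0.227 with fry. The simulated genes varied independently of each other, so this does not show how the preset correlation behaves for genes that move together. Every list statement below rests on the preset correlation.

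The type I interferon list was higher in knockout over all cells and in 13 of 15 classes, the exceptions being Plasma cell-like cells and the Xcl1-high cluster. Both knockout libraries lay above both wild-type libraries in mean log2 CPM of the list in 12 of the 13, the exception being Hepatocyte-like cells. In T cell-like cells the summed CPM overlapped (1897 and 1583 in wild type, 1925 and 1823 in knockout). Macrophage RNA may also be counted in other classes: Apoe, which leads macrophage cluster 1, had 10500 to 21710 CPM in NK-like cells. A rise within each class, apart from RNA of macrophages, was therefore not shown. In Monocyte/macrophage-like cells all 24 measured members lay above 0, with a median log2 fold change of 1.17; 14 rose with adjustment over all genes tested and 24 adjusted over the list alone (camera adjusted p 5.83e-41). The call was lost with an estimated correlation (adjusted p = 0.48). In Proliferating macrophage-like cells the median was 1.07 (camera adjusted p 1.22e-22; adjusted p = 0.893 with an estimated correlation) and in Kupffer-like cells 0.61 (1.72e-13; adjusted p = 0.508 with an estimated correlation), with no single member past the threshold in either. Over all cells Ifit3, Isg15 and Irf7 led the list, with a median of 0.97 over the 24 members (camera adjusted p 4.04e-30; adjusted p = 0.697 with an estimated correlation). The interferon gamma list was higher in Monocyte/macrophage-like cells (median 0.64 over 16 genes) and Neutrophil-like cells (0.98 over 9 genes), where Cxcl10, a chemokine, led both; with an estimated correlation the adjusted p was 0.48 and 0.594. The interferon gamma call was lost in clusters 1, 2 and 11 alone. Cxcl10 also leads macrophage cluster 3, so a change within Neutrophil-like cells was not shown.

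**Figure D3:**
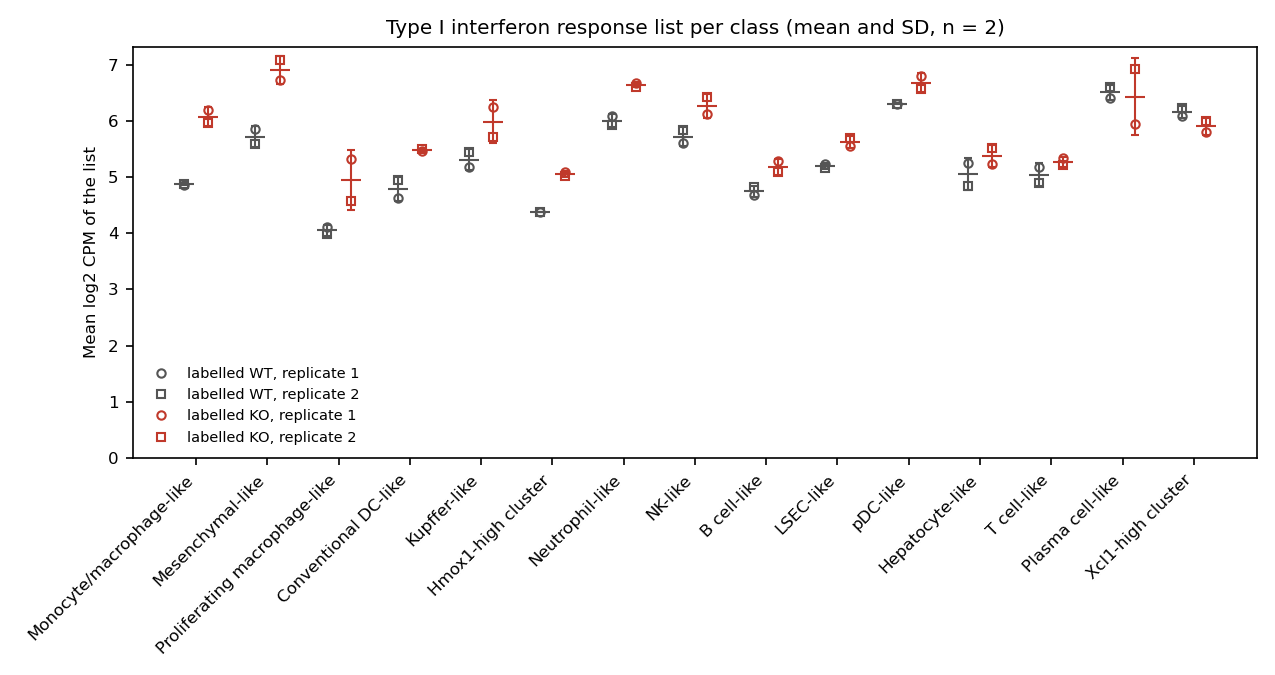
Mean log2 CPM of the measured type I interferon genes (vertical axis, from 0) per library and class, with marks for the mean and bars for the SD of 2 libraries. In Monocyte/macrophage-like cells both knockout libraries lie above both wild-type libraries.

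Antigen presentation genes lay higher over all cells, and those of MHC class II did not move 1 way across classes. Over all cells the 15 genes of the MHC class I list had a median log2 fold change of 0.27 (camera adjusted p 2.41e-06) and the 10 genes of the MHC class II list, among them H2-Eb1, H2-Aa and Cd74, of 0.44 (2.41e-06); with an estimated correlation the adjusted p was 0.697 for both. No member passed alone over all cells. Within classes the MHC class I list passed higher in 7 of 15, with an adjusted p of at least 0.606 with an estimated correlation. The MHC class II list passed higher in Mesenchymal-like (median 0.96) and pDC-like cells (0.19) and lower in LSEC-like cells (-0.98) and the Xcl1-high cluster (-0.92), the last 2 with overlapping libraries; with an estimated correlation the adjusted p was 0.606, 0.967, 0.955 and 0.797 in that order. In the Xcl1-high cluster the direction of the MHC class II list changed without wild-type replicate 1 (adjusted p 0.625), and the call was lost without knockout replicate 1 (0.317) or 2 (0.164). The call was also lost in LSEC-like cells without wild-type replicate 1 (0.933) or knockout replicate 1 (0.839), in Mesenchymal-like cells without knockout replicate 2 (0.197), and in pDC-like cells without wild-type replicate 2 (0.372), knockout replicate 1 (0.17) or knockout replicate 2 (0.206). The MHC class II rise was measured over all cells, where the shares of B cell-like and Conventional DC-like cells were also higher in both knockout libraries (10.9% against 14.02%, and 4.46% against 5.72%).

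Genes of Kupffer cells lay lower in other classes. The Kupffer identity list was lower in 10 of 15 classes, with both knockout libraries below both wild-type libraries in 7 of the 10, among them T cell-like cells (9 genes, median log2 fold change -1.55, camera adjusted p 5.40e-11, 3 members past the threshold; adjusted p = 0.663 with an estimated correlation) and B cell-like cells (9 genes, median -0.68, camera adjusted p 1.38e-07; adjusted p = 0.789 with an estimated correlation). Kupffer-like cells themselves did not pass (camera adjusted p 0.727). UMIs of Clec4f, Cd5l, Vsig4 and Marco made up 258 and 204 raw CPM in the B cell-like cells of wild type and 47.6 and 139 in knockout, and the share of Kupffer-like cells was also lower in both knockout libraries. In Mesenchymal-like cells, with 24 to 62 cells per library, the same list was higher (median 1.28, camera adjusted p 4.02e-10; adjusted p = 0.606 with an estimated correlation). The LSEC identity list, with Clec4g and Stab1, was lower in 8 of 14 classes (both knockout libraries below in 7 of the 8), with a median of -1.18 in B cell-like cells (adjusted p = 0.66 with an estimated correlation) and -0.86 in Monocyte/macrophage-like cells (adjusted p = 0.48 with an estimated correlation). Haemoglobin genes, which share reads between near-identical copies, had a median of -2.99 over all cells (4 genes, camera adjusted p 1.27e-05; adjusted p = 0.697 with an estimated correlation), none past the threshold alone.

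**Figure D4:**
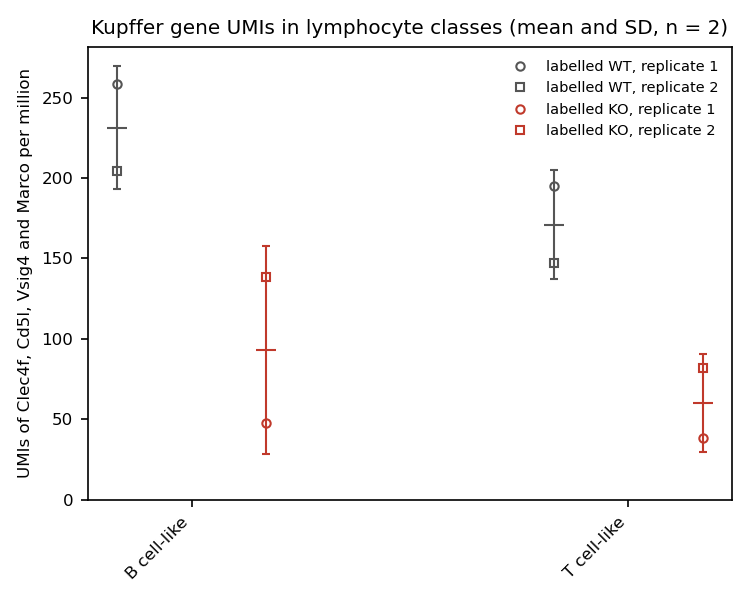
UMIs of Clec4f, Cd5l, Vsig4 and Marco in raw CPM (vertical axis, from 0) in B cell-like and T cell-like cells per library, with marks for the mean and bars for the SD of 2 libraries. In both classes the wild-type libraries lie above the knockout libraries.

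Mitochondrially encoded transcripts were lower in knockout over all cells (15 genes, median log2 fold change -0.51, camera adjusted p 9.94e-08; adjusted p = 0.697 with an estimated correlation) and in 14 of 15 classes, with a median of -1.26 in Neutrophil-like cells (adjusted p = 0.594 with an estimated correlation). The ribosomal RNA feature Rn18s-rs5 took 1.74% and 1.53% of the UMIs in wild type and 1.15% and 0.767% in knockout. Both are measures that also follow RNA and cell quality, and they moved with the genotype labels in the same libraries as the interferon and Kupffer genes.

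Cell cycle genes of the G2/M phase were lower in Hepatocyte-like cells (26 genes, median -1.25, camera adjusted p 3.75e-20; adjusted p = 0.868 with an estimated correlation), where Plk1, Hmmr and Cenpf had the smallest p, and in LSEC-like cells (30 genes, median -0.95, camera adjusted p 1.38e-20; adjusted p = 0.955 with an estimated correlation). The G2/M list also passed lower in Monocyte/macrophage-like (median -0.45), Neutrophil-like (-0.41) and T cell-like cells (-0.25) and higher in Kupffer-like cells (0.29), where the libraries overlapped; with an estimated correlation the adjusted p was 0.852, 0.692, 0.663 and 0.835 in that order. These calls were lost without wild-type replicate 1 (Monocyte/macrophage-like, 0.31), wild-type replicate 2 (Neutrophil-like, 0.0935, and T cell-like, 0.112) and knockout replicate 1 (Kupffer-like, 0.0597), and in Kupffer-like cells the G2/M list passed in the other direction without wild-type replicate 2. Endoplasmic reticulum stress genes were lower in Hepatocyte-like cells (14 genes, median -0.93), led by the chaperones Hsp90b1 and Dnajc3, and higher in Plasma cell-like cells (14 genes, median 0.51), led by Herpud1 and Pdia4; with an estimated correlation the adjusted p was 0.868 and 0.777. Complement and coagulation genes such as Plg and C9 were lower in Hepatocyte-like cells (18 genes, median -0.67, camera adjusted p 3.4e-05; adjusted p = 0.868 with an estimated correlation). The complement and coagulation call was lost without wild-type replicate 2 (adjusted p 0.375) and without cluster 32 (0.633). That cluster, led by Mup20, Alb and Apoa1, adds 33 cells with a median of 22338 UMIs to the summed Hepatocyte-like counts, 6 and 15 in wild type and 7 and 5 in knockout. No member of these lists passed alone.

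The lists nearest to the title gave few calls. CEBPA-dependent liver genes did not pass in Hepatocyte-like cells (10 genes, median -0.07, camera adjusted p 0.8) and of the 9 classes tested passed in Kupffer-like cells alone, where 4 genes were measured (median -0.33, camera adjusted p 0.0449; adjusted p = 0.508 with an estimated correlation) and Alb and Ttr are hepatocyte transcripts. DNA repair genes were lower in LSEC-like cells (21 genes, median -0.21, camera adjusted p 0.0326; adjusted p = 0.955 with an estimated correlation) and in Monocyte/macrophage-like cells (26 genes, median -0.23, camera adjusted p 0.00618; adjusted p = 0.814 with an estimated correlation), where the libraries of the genotypes overlapped. Targets of p53 were higher in Kupffer-like cells (21 genes, median 0.23, camera adjusted p 0.00861; adjusted p = 0.508 with an estimated correlation), led by Cdkn1a. Hepatic progenitor genes were lower over all cells (14 genes, median -0.33, camera adjusted p 0.0258; adjusted p = 0.697 with an estimated correlation), led by Krt19 and Krt7, and in Hepatocyte-like cells (4 genes, median -0.69, camera adjusted p 0.0132; adjusted p = 0.868 with an estimated correlation) and Mesenchymal-like cells (5 genes, median -1.45, camera adjusted p 0.0179; adjusted p = 0.606 with an estimated correlation). The hematopoietic stem and progenitor list was higher in Mesenchymal-like cells (4 genes, median 0.55, camera adjusted p 0.0189; adjusted p = 0.606 with an estimated correlation), 1 of 6 classes tested. In Mesenchymal-like cells the hematopoietic call was lost without knockout replicate 1 or 2 (adjusted p up to 0.126), and the hepatic progenitor call without wild-type replicate 2 or knockout replicate 1 (up to 0.21). Over all cells the hepatic progenitor call was lost without wild-type replicate 2 or knockout replicate 1 (up to 0.336), and in Hepatocyte-like cells without any 1 of the 4 libraries (up to 0.483). The CEBPA call in Kupffer-like cells was lost without wild-type replicate 2 or either knockout library (up to 0.293), and the p53 call without wild-type replicate 1 or knockout replicate 2 (up to 0.169). The DNA repair call was lost in LSEC-like cells without wild-type replicate 2 or knockout replicate 2 (up to 0.482) and in Monocyte/macrophage-like cells without wild-type replicate 1 or knockout replicate 2 (up to 0.793). The lists of m6A readers, of m6A writers and erasers, of the C/EBP family, of hepatocellular carcinoma and of Wnt targets passed in no class in which they were tested. Cholangiocyte-like cells, a source of Krt19 and Krt7, made up 0.260% of the cells in wild type and 0.261% in knockout and were too few to test.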

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

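In this part, the tests on cluster 3, on free RNA in the interferon pattern, on the Kupffer-like cells, on cells with many Kupffer UMIs and on the level of Ythdf3 were chosen after the result was seen; only the correlation across Kupffer genes was set down before.

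The higher type I interferon genes in Monocyte/macrophage-like cells of the libraries labelled knockout could come from more cells of the interferon-led cluster 3. Outside that cluster the list's median log2 fold change was still 1.03, against 1.17 in the whole class, with both knockout libraries above both wild-type libraries, although the count of single genes fell from 26 to 0. Free RNA shared by all classes is argued against by B cell-like and T cell-like cells, where the summed CPM of the list rose by at most 0.259 of the 1996 in Monocyte/macrophage-like cells, and by Hepatocyte-like cells and the Xcl1-high cluster, with changes of 37.7 and -143, while it rose by 1125 in Neutrophil-like and 2189 in Mesenchymal-like cells, where free RNA was not tested apart from their own expression. What stays open, and was not tested, is whether the difference follows the Ythdf3 genotype or something else that differed between the mice or preparations, such as an infection or the lower mitochondrial and Rn18s-rs5 content of the same libraries.

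The lower Kupffer genes in B cell-like and T cell-like cells could reflect lower expression in Kupffer cells. Within Kupffer-like cells the Kupffer identity list had a median log2 fold change of -0.0442. This cannot decide the question, since the class was named from markers that include members of the list. Cells with lower levels of them could fall outside the class. Kupffer cells or doublets among the lymphocytes are argued against by 8.02% of the UMIs of Clec4f, Cd5l, Vsig4 and Marco in T cell-like cells lying in cells with 5 or more of them. Free RNA from Kupffer cells may contribute. Across 13 genes, which are not independent replicates, the level in wild-type lymphocytes followed that in Kupffer-like cells. Pearson r was 0.804, just at its bound of 0.8, and Spearman rho was 0.874. Both used wild-type cells alone, so they cannot decide on the difference between genotypes. Kupffer-like cells were fewer in both knockout libraries. The list summed to 2041 and 2728 raw CPM over all cells in wild type and 1515 and 1866 in knockout. In T cell-like cells the sums were 484.6 and 362.1 against 180.8 and 220.7. In B cell-like cells they were 607.6 and 547.7 against 251.8 and 472.8. Wild-type replicate 2 was the higher of its pair over all cells but the lower in both lymphocyte classes. No other biological explanation was tested.

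Ythdf3 was not lower in the libraries labelled knockout. A deletion away from the counted 3′ end could leave the counts as they are (log2 fold change 0.10), and this cannot be told apart from libraries without the deletion, because the deletion site is not given. A swap between the genotypes stays open for the same reason: the lowest wild-type library had 0.918 of the CPM of the highest library labelled knockout, and an allele that leaves the 3′ counts as they are would give equal levels with or without a swap.

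Lists that passed in opposite directions in different classes, with every knockout library on 1 side in each, were set apart as differences between classes; these differences were not tested, and every call was lost with an estimated correlation (adjusted p of at least 0.508 in these classes). The gap between the class differences in mean log2 CPM was 2.94 for Kupffer identity (higher in Mesenchymal-like cells, lower in the Xcl1-high cluster). It was 1.25 for endothelial capillarisation (higher in Mesenchymal-like, lower in Monocyte/macrophage-like cells), where the member Ly6a rose in the second. Endoplasmic reticulum stress gave 1.20 (higher in Plasma cell-like, lower in Hepatocyte-like cells). Inflammatory cytokines and chemokines gave 1.04 (higher in Kupffer-like, lower in pDC-like cells), and S phase 1.04 (higher in the Xcl1-high cluster, lower in pDC-like cells). With 1 library left out the calls for endothelial capillarisation (adjusted p up to 0.193 in Mesenchymal-like and 0.262 in Monocyte/macrophage-like cells), inflammatory cytokines (0.242 in Kupffer-like and 0.39 in pDC-like cells) and S phase (0.399 in pDC-like cells) were lost as well: without knockout replicate 1, wild-type replicate 1, knockout replicate 2 and knockout replicate 1 in that order, and for S phase without wild-type replicate 1 or either knockout library.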

How the results depend on the processing

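Settings without a fixed plan, the macrophage clusters among them, were chosen after the data were seen; in a fit without 1 library the lone sample is assumed to vary like the other group, and the cause of the changes was not tested. Over all cells 1 gene passed, against 74 with DESeq2, 515 without the count filter, 0 to 6 with 1 library left out and 1 with the replicate block, which was not the same gene. Over the classes 52 became 116 with DESeq2, 1080 unfiltered, 317 to 794 with a library left out, 640 with the block, and 14 at Leiden resolution 0.5, where 13 classes were fitted that held 47 of the 52. In Monocyte/macrophage-like cells 26 became 74 with DESeq2, 191 unfiltered, 10 to 166 with a library left out, 302 with the block, 11 with doublets kept, 4 at resolution 0.5, 5 with all macrophages merged, 0 without cluster 3, and 2, 2, 0, 1 and 24 in clusters 1, 2, 3, 11 and 15 alone. In T cell-like cells 13 became 1 with DESeq2, 52 unfiltered, 0 to 123 with a library left out, 43 with the block, 5 with doublets kept and 0 at resolution 0.5. In B cell-like cells 4 became 1, 48, 6 to 78 and 2 with DESeq2, unfiltered, a library left out and the block. In the Hmox1-high cluster 5 became 3, 27, 18 to 27 and 61 in that order, 3 without the mitochondrial limit, and 0 with doublets kept or ComBat; 1 of the 5 changed sign without knockout replicate 2 and with doublets kept. In pDC-like cells 3 became 0, 27, 8 to 71 and 27, and 0 with ComBat; in Plasma cell-like cells 1 became 6, 137, 0 to 375 and 23, and 0 without the mitochondrial limit. In the classes with 0 calls (Conventional DC-like, Hepatocyte-like, Kupffer-like, LSEC-like, Mesenchymal-like, Neutrophil-like, NK-like, Proliferating macrophage-like, Xcl1-high cluster) the block gave 47, 19, 2, 0, 30, 0, 4, 80 and 0 calls and the unfiltered test 53, 18, 104, 195, 68, 31, 6, 44 and 79. With doublets kept these classes gave 0, 0, 0, 3, 0, 3, 9, 0 and 1 calls in that order. Over all tested classes doublets kept gave 40 calls, of which 22 were among the 52. Of the 116 with DESeq2, 29 were among the 52, and the 1 in B cell-like cells was not. No class share passed, against 1 with hepatocytes out of the denominator, 1 with doublets kept and 0 to 3 with a library left out; for Low-UMI cluster 16 the block gave an adjusted p of 0.316. Of 166 list tests that passed, 0 passed with an estimated correlation and 0 with fry's directional test; the block passed 161, of which 158 were among the 166. Without wild-type replicate 1 or 2 or knockout replicate 1 or 2, 170, 193, 161 and 175 passed, of which 113, 121, 105 and 119 were among the 166; 2 of these passed in the other direction without wild-type replicate 2. In Monocyte/macrophage-like cells camera's direction changed for the interferon gamma list in cluster 11 alone (adjusted p 0.438) and for the LSEC identity list in cluster 15 alone (adjusted p 0.886). The direction of the MHC class II list in the Xcl1-high cluster changed without wild-type replicate 1 (adjusted p 0.625); over the libraries left out its adjusted p lay between 2.36e-08 and 0.625. The G2/M list changed direction in Kupffer-like cells without wild-type replicate 2 (adjusted p 0.00238; between 4.76e-29 and 0.0597 over the libraries left out) and in Monocyte/macrophage-like cells with all macrophages merged (adjusted p 0.551). The share of dividing cells differed by -0.461 percentage points, and by -2.854 without thinning. Of the 26 named genes that passed, 12 passed with DESeq2, and none of these 26 changed sign in any setting tried. The labels do not say what the replicate numbers share; libraries with the same number had a correlation of deviations of -0.0449 over all cells, 0.199 in Monocyte/macrophage-like, 0.257 in Proliferating macrophage-like and 0.129 in Hmox1-high cells, and down to -0.166 in B cell-like cells, so the block may or may not follow a real pairing.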

Other observations

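In the Xcl1-high cluster, cells that carry Xcl1, Nkg7 and T cell receptor transcripts, cytotoxic genes lay higher in the knockout-labelled libraries. The cytotoxic effector list had a median log2 fold change of 0.40 over 11 genes (camera adjusted p 7.65e-05; adjusted p = 0.678 with an estimated correlation), with Gzma (1.85, SE 0.27), Prf1 (1.28), Ccl5 (1.06) and Gzmb (0.99) among them. DNA replication genes of the S phase list had a median of 0.58 over 20 genes (9.32e-11; adjusted p = 0.734 with an estimated correlation), with Mcm5 (1.49) and Dut (0.85) among them, and the T cell exhaustion list a median of 1.23 over 4 genes (0.000202; adjusted p = 0.678 with an estimated correlation), with Tox (1.58) and Lag3 (2.36). No member passed alone, and Rn18s-rs5 had a log2 fold change of -0.997 in the same cells. Gzma, Prf1 and Ccl5 are also among the 10 leading genes of NK-like cluster 18, the NK-like share was higher in both knockout libraries (1.17% and 0.724% against 1.23% and 1.70%), and the Kupffer identity list was lower in the Xcl1-high cluster (median -1.43; adjusted p = 0.678 with an estimated correlation), so a change within these cells was not shown. Matrix genes were counted less in macrophage classes: the stellate activation list had a median of -0.62 over 14 genes in Monocyte/macrophage-like cells (7.48e-08; adjusted p = 0.48 with an estimated correlation), where Sparc alone passed (-1.40, adjusted p 0.0498), and of -0.90 over 9 genes in Kupffer-like cells (1.09e-05; adjusted p = 0.508 with an estimated correlation). The LSEC identity list was also lower in Monocyte/macrophage-like cells (-0.86), and the classes that carry these genes had lower mean shares in knockout (LSEC-like 6.28% to 3.02%, Mesenchymal-like 0.646% to 0.407%, the second with overlapping libraries), so a change within macrophages was not shown.

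The genes beside Ythdf3 on its chromosome were examined as a hypothesis that the targeted allele changes them; this test, its 5 groups of cells and the genes Rbis and Lrrcc1 were chosen after values of Rbis had been seen. The 20 genes were the nearest 10 tested genes on each side, with the gene order from the GRCm38 annotation, while the counts are on GRCm39. Over all cells 5 of the 20 had an unadjusted p under 0.05 in edgeR's test, 4 on one side and 1 on the other, against 5.82% of all genes. The bound, which each side had to reach on its own, was not met. As many or more such neighbours were found around 2.23% of all genes used as a centre; in Monocyte/macrophage-like, Kupffer-like, B cell-like and T cell-like cells the share was 7.99%, 25.4%, 1.80% and 0.0242%. The 5 neighbours did not move 1 way over all cells: Rbis (-0.841), Lrrcc1 (-0.451) and Cyp7b1 (-0.999) were lower, Sirpb1a (0.628) and Sirpb1c (0.325) higher. Rbis had a log2 fold change between -1.20 and -0.61 in the 14 classes that measured it, below 0 in all 14, with a lowest adjusted p of 0.166. Both knockout libraries lay below both wild-type libraries for Rbis in 13. Lrrcc1 was below 0 in 10 of 11, with both below in 5 and an unadjusted p under 0.05 in 2. None passed, and the Sirpb1 genes among the neighbours are near copies of each other, so the test cannot tell a change at the locus from chance or from background variants carried along with a targeted allele; the hypothesis may merit a test at the genomic level.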
